A study of Bacillus subtilis with 2 samples.

How the data were processed

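Total RNA of Bacillus subtilis W168, wild type and the rocG gudB double deletion mutant, was taken from cultures in LB at an OD600 of 0.4, per the labels' protocols. Of it, 20 µg was turned into labelled cDNA with indirect Alexa Fluor labelling, per the labels' protocols. Each of the 2 samples is an array that holds the wild type in channel 1 and the mutant in channel 2, in the same dye orientation, per the labels. The design text speaks of an experiment done 2 times with 3 independent RNA preparations, and does not say which preparation is on which array. The arrays were therefore treated as 2 replicates of 1 comparison, and their number limits the precision.

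The values used were the deposited log2 ratios of the series' value table, with 4116 lines, 1 per gene or control spot. The scanner, background correction, normalization and any filter are not given in the sources used here, and scanner files were not used here. The log base was settled from the values, since 2 to the power of the size of most large values is a multiple of 0.5. Centring was not applied, as the medians of 4.24 and 2.33 show, and the direction was taken from the dyes and from gudB, which was at the negative end on both arrays. A value was taken to have one channel at a floor of 1 where 2 to the power of its size lay on a multiple of 0.5 within the tolerance given by 4 deposited decimals. Positive values of this kind were assigned to a wild-type channel at the floor, negative ones to a mutant channel at the floor, exact zeros were kept apart (259 and 156 genes), and all others were taken as measured in both channels. On simulated spot pairs this rule recovered 97.0% of pairs measured in both channels. A small ratio such as 1.5 can also come from 2 measured signals, and it is then counted at the floor. Hits through the tolerance alone grow with size: on array 1 chance gives 0.033% between 0 and 2 and 3.98% above 6. The class assignment was made after the values were seen, and 10 control spots were left out of all tests.

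Gene names are those of the table. Of 4106 names, 3036 matched a current symbol in the ASM904v1 annotation of strain 168, which was used only for gene order. The other 1070 did not, so members of gene lists under newer names were not found. Every gene had 1 line.

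The test was limma 3.58.1 in R 4.3.3, with lmFit on an intercept alone and eBayes on the 4102 genes with both values, against a ratio of 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 residual degree of freedom per gene, the prior degrees of freedom were 1.11. After median centring they were infinite, so that all genes then shared 1 variance. On simulated data for the 4102 genes with 200 of them changed, the adjusted test recovered 0% of changes of log2 2, 4 and 8 (59.7%, 65.7% and 90.9% at an unadjusted p of 0.05) and called 0 unchanged genes. For the real ratios as deposited, calls were thus unlikely unless a large part of all genes lay away from 0. A count of genes at least 2-fold from 0 on both arrays had been fixed before the data were examined as a further measure, because of the 1 residual degree of freedom. Gene lists were fixed before the data were examined, and 31 of them with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, and then with an estimated one. Lists for proline use and cannibalism toxins had 0 measured members and the biofilm matrix list had 2, so they were not tested. In the simulation a list lowered by log2 2 was called and 0 others were. With 1 residual degree of freedom the estimated correlation carries little information, and that form of camera could hardly call any list. A call that ended under it therefore weighs little either way.

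Genes named in the text are rocG and gudB, and the 10 with the highest and the 10 with the lowest mean among genes past the adjusted threshold with the same sign on both arrays. Further names were drawn from the 4 members with the largest absolute mean of each list that was called or had at least 3 members past the test. Not all of these members are named. The neighbours of the deleted genes are named too. The rule of highest and lowest means orders genes by single-channel signal where a channel was at the floor. Names chosen after the values were seen are marked.

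Alternatives fixed before the data were examined were median centring, centring with scaling, quantile normalization, robust eBayes and treat against a fold of 1.2. Further ones were an adjusted p of 0.1, removal of genes whose arrays differ by more than 1, a pooled variance, folds of 1.5 and 3, a mean of at least 2-fold, an estimated correlation, 10000 random lists, fry, and leaving out each array. Alternatives added after seeing the data were restrictions to genes measured in both channels, as deposited and centred on their median, and to genes with the wild type at the floor. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.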

Results

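Transcript levels of wild-type Bacillus subtilis W168, a laboratory strain of this spore-forming soil bacterium, were set against those of a double mutant lacking rocG and gudB. These genes encode the glutamate dehydrogenases of this species, the enzymes that turn glutamate into oxoglutarate and ammonium. Enzyme activity was not measured here, so these data do not show whether either was active in the wild type. Both strains had been grown in LB, a rich broth, to an OD600 of 0.4. Total RNA of both strains was hybridised together on each of 2 dual-colour arrays, replicates 1 and 2, with the wild type in the same dye on both. A dye effect therefore cannot be separated from the genotype. The deposited table held 1 log2 ratio per gene and array for 4106 genes and for 10 control spots named for BMV RNAs and Escherichia coli genes. Of the genes, 4102 had a value on both arrays. Ratios are given as mutant over wild type, a direction that is likely rather than stated, from the dyes in the labels and from gudB. With 2 arrays, each gene had 1 residual degree of freedom. How the 3 RNA preparations of the design text were spread over the arrays is not given in the sources used here, and p-values therefore measure only the spread between these arrays, which may be technical.

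What a ratio stood for differed between genes. On array 1, 97.5% of the 2121 values above 4 were the log2 of a multiple of 0.5 within the rounding of the 4 deposited decimals, where chance gives 2.63%. On array 2 this held for 97.0% of 1613 values, where chance gives 1.38%. Such a value arises where the other channel was set to a floor of 1, so that it is the log2 of a single channel's signal and no measured ratio. The wild-type channel lay at this floor for 2444 genes (59.5%) on array 1 and 2032 genes (49.5%) on array 2, and the mutant channel for 80 genes (1.95%) and 112 genes (2.73%). Both channels were measured for 1322 genes (32.2%) on array 1 and 1803 genes (43.9%) on array 2, and on both arrays for 1183 genes. The median ratio over genes was 4.24 on array 1 and 2.33 on array 2, whereas among the 1183 genes measured in both channels throughout it was 0.09 (SD over genes 1.92) and -0.37 (SD 1.07). The control spots had medians of 4.19 and 3.99. No fold is given below for a gene with a channel at the floor, and a comparison of such values between genes would compare spots, not changes.

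**Figure D1:**
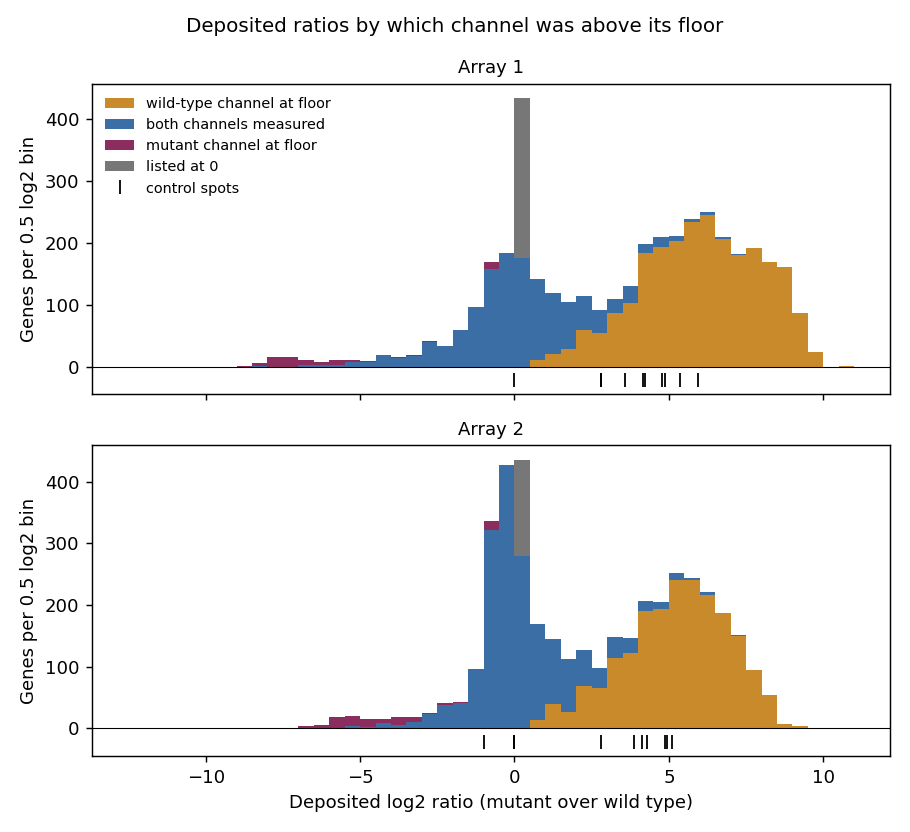
Number of genes per 0.5 log2 bin of the deposited ratio (mutant over wild type) on each array, stacked by which channel was above its floor, with the 10 control spots as ticks. Values from genes with the wild-type channel at the floor make up most of the hump right of 2, and genes measured in both channels lie around 0. The control spots' medians of 4.19 and 3.99 fall within the range of the hump.

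The 2 deleted genes read differently. The gudB spot was at -8.27 on array 1, measured in both channels, and at -12.02 on array 2. There the rule placed the mutant channel at the floor, with a wild-type signal of 4140.5 units. At so large a value the tolerance from 4 decimals is too wide to settle this class. The mean of gudB was -10.14 ± 2.65 (SD, n = 2, limma adjusted p = 0.0471). Since the direction of the ratios was taken in part from this gene, its sign is no separate check of that direction. The rocG spot was at 2.32 and 4.83, with the wild type at the floor on both arrays and mutant-channel signals of 5.0 and 28.5 units. These lay within the range of the control spots, whose highest signals were 62.0 and 34.0 units, so that a rocG transcript was not detectable above background in either strain (mean 3.58 ± 1.78, SD, n = 2, adjusted p = 0.135). Where the spots lie relative to the deleted parts of either gene is not given in the sources used here.

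The comparison of mutant and wild type asks which transcripts differ where both glutamate dehydrogenase genes are missing. Of the arginine and ornithine breakdown genes, whose products feed into glutamate, 6 of 7 were called higher in the mutant channel, with no wild-type signal above the floor on either array. Their means ran from 9.84 for rocA down to 5.56 for rocR. Also called were the 3 genes of the glutamate synthase list, at means from 7.11 for gltC to 8.96 for gltB. Of these gltA and gltB encode the enzyme, which makes glutamate from glutamine and oxoglutarate, and gltC encodes their activator. Among genes measured in both channels, those for ribosomal proteins, for the envelope-stress regulon of sigma W and for the citric acid cycle lay below the other genes as groups, by medians of -0.74, -0.82 and -0.57 after centring on these genes. The last lay within the central 95% of random lists. None of the 3 lists was called by camera with an estimated correlation (adjusted p = 0.956 for each). With 1 residual degree of freedom that form could hardly call any list. In the limma test 1351 of 4102 genes passed an adjusted p of 0.05, 1328 of them higher in the mutant and 23 lower. Of the higher ones, 1309 had the wild-type channel at the floor on both arrays, and 2 were measured in both channels on both arrays. Of the 1328 genes, 669 lay above all control spots on both arrays. Of the genes called higher and named below, carB lay within the range of the control spots on both arrays, rocR, argC, proI, spo0A, comGA, spsJ and ypbG on array 1, and spsK on array 2. By the size of the ratio, jag and yccG also lay under the highest control spots, at 5.95 and 5.09, on both arrays. Both channels were measured for these genes, so their signals are not known.

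These counts rest on where 0 is set. After subtraction of each array's median, 298 genes passed, 50 higher and 248 lower, and the share of higher calls was 16.8% in place of 98.3%. All of these 50 and 23 of the 248 had passed in that direction before. At an unadjusted p of 0.05, 1740 genes passed as deposited (1655 higher, 85 lower). By the rule of size fixed before the data were examined, 2357 genes were at least 2-fold from 0 in the same direction on both arrays, 2132 higher and 225 lower, against 1642 and 31.9 for independent arrays. The figure for independent arrays ignores that 1754 genes had the wild type at the floor on both arrays, where values can only be positive. The excess of higher genes therefore shows no repeated change by itself. By the same rule of size, 1064 were higher and 1317 lower after median centring. Restricted to the 1183 genes measured in both channels and centred on their median, a choice made after seeing the data, limma called 0 genes (smallest adjusted p = 0.358), with 135 at an unadjusted p of 0.05, 57 higher and 78 lower. Of these genes, 76 were higher and 90 lower by at least 2-fold on both arrays, where independent arrays would give 31.5 and 24.7.

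Across the 4102 genes the arrays correlated with Pearson's r = 0.587 and Spearman's rho = 0.598, and 77.9% of genes had the same sign on both. Within the genes measured in both channels r was 0.521 and rho 0.614, and within the 1754 genes with the wild type at the floor on both arrays r was 0.614 and rho 0.674. These correlations are across genes, which are not independent replicates. The arrays parted over 570 genes that had the wild type at the floor on array 1 and both channels measured on array 2. Their median was 8.22 (SD over genes 1.32) on the former and 1.13 (SD 1.56) on the latter. The leucine synthesis genes leuB and leuC were among them, at 9.61 and 9.55 on array 1 and at 3.10 and 3.51 on array 2.

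**Figure D2:**
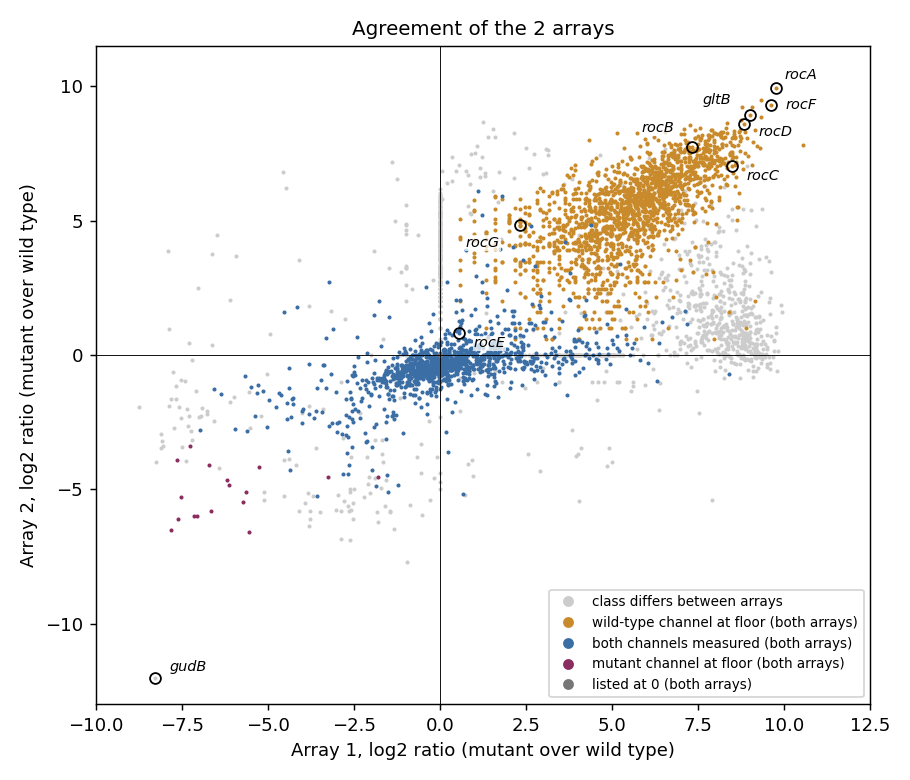
Deposited log2 ratio (mutant over wild type) of each gene on array 1 (x axis) and array 2 (y axis), coloured by which channel was above its floor on both arrays, with named genes ringed. The genes with the wild-type channel at the floor on both arrays run up to rocA at 9.76 and 9.93, gudB lies at -8.27 and -12.02, and a group of grey points high on array 1 lies near 0 on array 2.

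Of the 7 measured genes of arginine and ornithine breakdown other than rocG, 6 were called higher, and 6 also adjusted over the list alone. The pyrroline-carboxylate dehydrogenase gene rocA was at 9.76 and 9.93 (mean 9.84 ± 0.12, SD, n = 2, adjusted p = 0.0323). The others were the arginase gene rocF at 9.61 and 9.29, the ornithine aminotransferase gene rocD at 8.83 and 8.60, the permease gene rocC at 8.49 and 7.03, rocB at 7.31 and 7.75 and the regulator gene rocR at 5.41 and 5.71. All 6 had the wild-type channel at the floor on both arrays, with mutant-channel signals of 865 and 976 units for rocA. Those of rocR were 42.5 and 52.5 units, the former within the range of the control spots on its array. The permease gene rocE was the exception: measured in both channels, it stood at 0.55 and 0.82 (mean 0.69 ± 0.19, SD, n = 2, adjusted p = 0.362), and its sign turned under centring on the median of all genes, to -2.60. Centred on the genes measured in both channels it was at 0.83 (unadjusted p = 0.144). With centring, rocA (adjusted p = 0.00228), rocF (0.00474) and rocD (0.0185) stayed past the test, and rocB (0.0799), rocC (0.0680) and rocR (0.312) did not. As all genes then shared 1 variance, these p-values only follow the size of the mean. The list was called higher by limma camera with a preset correlation of 0.01 (adjusted p = 0.0226). It was not called with an estimated correlation (adjusted p = 0.776), a form that could hardly call any list. With 6 members at the wild-type floor this sets spot signals against those of other genes, and among genes with the wild type at the floor alone the list was not called (adjusted p = 0.0925).

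The 3 genes of the glutamate synthase list were called higher, also adjusted over the list alone (3 of 3). The large-subunit gene gltA was at 7.27 and 8.56, gltB at 9.00 and 8.92 (mean 8.96 ± 0.06, SD, n = 2, adjusted p = 0.0323) and their activator gene gltC at 7.41 and 6.80, all with the wild type at the floor. After median centring, where p-values only follow the size of the mean, gltB was past the test (adjusted p = 0.0121) and gltA (0.0585) and gltC (0.104) were not. The list itself was not called by camera (adjusted p = 0.0911), but it was by random lists (percentile 99.9) and by fry (adjusted p = 0.0260). With all members at the wild-type floor, camera and random lists set spot signals against those of other genes. Fry sets the list against 0, and values at the wild-type floor can only be positive, so its higher direction was given beforehand.

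Other nitrogen and amino acid genes were mixed, and their counts stand beside the 1328 of all 4102 genes that were called higher. Among the 1754 genes with the wild type at the floor on both arrays 1309 were called higher. A list's count therefore depends in part on how many members lay there. Of the TnrA and GlnR genes below 8 did, and the 4 measured in both channels had a centred median of -0.03. Of 16 genes controlled by the nitrogen regulators TnrA and GlnR, 8 were called higher (8 adjusted over the list alone), among them the nitrite reductase genes nasD and nasE, nasF at 7.51 and 7.65, and tnrA at 6.77 and 6.28. Of 6 proline synthesis genes, 4 were called higher (4 adjusted over the list alone): proG, proH, proJ and proI, at means of 7.43, 7.35, 7.26 and 5.55. Of 6 histidine breakdown genes, hutM and hutP were called higher at means of 6.72 and 6.69. The urocanase gene hutU was called lower at -7.51 and -5.30 with the mutant channel at the floor, and hutG, at 5.11 and 2.70, did not pass (4 passed when adjusted over the list alone). Of 14 transport genes repressed by CodY, 6 were called higher (7 adjusted over the list alone), including the peptide transport genes appA, appB and dppB at means of 8.41, 6.47 and 6.80. Of 9 arginine synthesis genes, 3 were called higher (4 adjusted over the list alone), argC and carB among them at means of 5.52 and 4.34. With median centring appA stayed past the test (adjusted p = 0.0309), hutU stayed lower, and the other calls named here ended, with adjusted p-values from 0.0780 for nasF to 0.630 for carB. None of these lists was called by camera, with adjusted p-values of 0.538 for the TnrA and GlnR genes, 0.342 for proline synthesis, 0.818 for histidine breakdown, 0.200 for the CodY genes and 0.475 for arginine synthesis. Random lists called proline synthesis higher (percentile 99.6). None of the 10 branched-chain amino acid genes passed the limma test over all genes or adjusted over the list alone, although the list lay below the other genes by camera (adjusted p = 0.0471). That call was lost with random lists (percentile 3.88, within the central 95%). It was also lost with an estimated correlation (adjusted p = 0.776), a form that could hardly call any list. Members of the branched-chain list spread from leuA, at -1.80 and -6.22, to leuD, at 8.63 and 5.02.

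Camera called 13 lists lower than the other genes in all. Apart from the branched-chain list, most members of each were measured in both channels, and so lay near 0 while the median gene did not. Their adjusted p-values were 3.22e-20 for ribosomal proteins, 1.38e-14 for sigma W, 7.91e-08 for the citric acid cycle, 1.66e-06 for iron uptake genes of the Fur regulon and 3.08e-05 for glycolysis. They were 2.63e-04 both for ATP synthase and for general stress genes of sigma B, 0.00242 for motility and chemotaxis, 0.00281 for peptidoglycan synthesis, 0.00420 for heat shock and Clp genes, 0.00447 for purine synthesis and 0.0152 for overflow metabolism. Single genes called by limma in some of these lists went the other way. Called higher were 5 motility genes, 2 overflow genes and 1 each of the peptidoglycan, sigma B and heat shock lists. Among them were fliD and dat, at means of 8.01 and 8.33 with the wild type at the floor, and 0 members of these lists were called lower. With an estimated correlation, a form that could hardly call any list, 0 lists were called (smallest adjusted p = 0.776). Among the genes measured in both channels 3 of 21 lists stayed lower, with or without centring: ribosomal proteins (adjusted p = 2.9e-05), sigma W (5.73e-04) and the citric acid cycle (0.0175). By the median among random lists of such genes, ribosomal proteins and sigma W lay outside the central 95%, and the citric acid cycle, at percentile 2.83, lay within it. With an estimated correlation none of these was called (smallest adjusted p = 0.956).

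Ribosomal protein genes measured in both channels numbered 47, and 36 of them (76.6%) lay below the median of such genes on both arrays, against 37.0% of all 1183. The members with the largest means were rpsC at -2.10 and -0.995, rplO at -1.82 and -0.925, rplP at -1.78 and -0.932 and rplF at -1.82 and -0.840, and none of the 47 passed the limma test on its own. Of the 36 sigma W genes measured in both channels, 25 (69.4%) lay below the median on both arrays, among them ydjH at -2.93 and -2.50 (adjusted p = 0.0616) and yuaF at -2.53 and -1.82. The sigma W gene yuaI went the other way and was called higher at 6.76 and 6.28, with the wild type at the floor, but the call ended with median centring (adjusted p = 0.148), and 0 members passed when adjusted over the list alone. Of the 11 citric acid cycle genes measured in both channels, 8 (72.7%) lay below the median on both arrays. The isocitrate dehydrogenase gene icd was at -2.54 and -2.50 (mean -2.52 ± 0.03, SD, n = 2, adjusted p = 0.0629), the malate dehydrogenase gene mdh at -4.62 and -1.49, the citrate synthase gene citZ at -4.40 and -1.22, and the fumarase gene citG at -7.32, with the mutant channel at the floor, and -2.63. None of the 12 measured members passed over all genes or adjusted over the list alone.

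**Figure D3:**
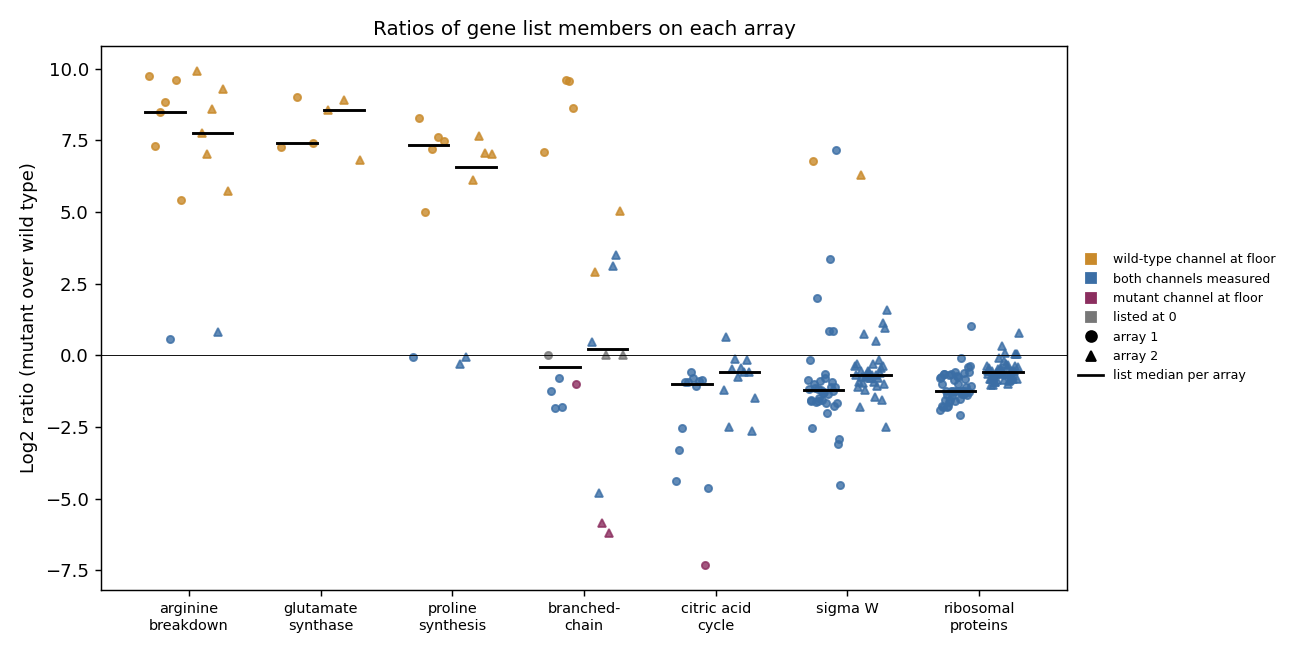
Deposited log2 ratio (mutant over wild type) of the members of 7 gene lists on array 1 (circles) and array 2 (triangles), coloured by which channel was above its floor, with a bar for each list's median per array. The roc list has medians of 8.49 and 7.75 with rocE apart at 0.55 and 0.82, and the ribosomal protein list has medians of -1.24 and -0.58.

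Of the remaining lists, sigma M genes numbered 21, with 6 called higher (6 adjusted over the list alone), such as ydbO and the anti-sigma factor genes yhdL and yhdK at means of 7.33, 7.74 and 7.59, and ypuA called lower at -5.10 and -5.39. Competence genes were called higher in 6 of 20 cases, comGA among them at a mean of 5.71, and early sporulation genes in 5 of 13, spo0F and spo0A among them at 8.58 and 6.27. PBSX prophage genes were called higher in 7 of 28 cases, xtmA and xkdS among them at 6.53 and 6.51. For ICEBs1 genes it was 5 of 17, phrI among them at 7.24, and for carbon source genes under catabolite repression 8 of 31, lcfA and iolD among them at 7.74 and 7.55. Adjusted over the list alone these were 7, 7, 7, 4 and 8 genes called higher. Such counts, too, stand beside the 1309 called higher among the 1754 genes with the wild type at the floor on both arrays. With median centring spo0F stayed past the test (adjusted p = 0.0240), ypuA stayed lower, and the other calls named here ended, with adjusted p-values from 0.0693 for lcfA to 0.280 for comGA. The adjusted p-values from camera were 0.184 for sigma M, 0.635 for competence, 0.538 for early sporulation, 0.583 for PBSX, 0.840 for ICEBs1 and 0.587 for the carbon source genes. Tryptophan synthesis (0.587), pyrimidine synthesis (0.818), the PerR regulon (0.424), cysteine and methionine genes (0.714) and the sigma X and sigma V regulons (0.0633) were not called. Random lists of all genes called sigma M (percentile 0.670) and the sigma X and sigma V regulons (1.84) lower. Among genes measured in both channels these lists lay at percentiles 45.6 and 14.9. Among genes with the wild type at the floor sigma M lay at 99.5, so the lower calls depend on how members spread over these classes.

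The 10 genes called higher with the largest means were rocA, rocF, yhcB, yxaA, the spore coat gene cotE, ywfI, the spore coat assembly gene safA, gltB, yolJ and ywcJ. All had the wild type at the floor on both arrays, with means from 9.84 for rocA to 8.75 for ywcJ. Their arrays differed by less than 1 except for yxaA, at 10.54 and 7.82 (mean 9.18 ± 1.92, SD, n = 2, adjusted p = 0.0380). After gudB, the genes called lower with the largest means were the thymidylate kinase gene tmk, at -7.82 and -6.51 (mean -7.16 ± 0.93, SD, n = 2, adjusted p = 0.0324). They were followed by yhdJ, ytpB, yabJ, hutU, the fatty acid synthesis gene fabL at -6.67 and -5.81, the sporulation gene spoIIR, yloS and yuzB, the last at a mean of -5.49. All of these had the mutant channel at the floor on both arrays. The 4 called genes that were measured in both channels on both arrays, named for that reason after their values were seen, were jag at 4.39 and 4.82 and yccG at 3.63 and 4.22, both higher, with the germination genes sleB at -4.36 and -4.27 and gerPF at -4.42 and -3.56, both lower. After centring on the median of all genes, which moves every gene down, jag (adjusted p = 0.556) and yccG (0.768) no longer passed. Under it sleB (2.44e-04) and gerPF (4.82e-04) stayed lower. Centred on the genes measured in both channels, jag and yccG were at 4.75 (unadjusted p = 0.00178) and 4.07 (unadjusted p = 0.00333). There sleB and gerPF were at -4.17 (unadjusted p = 0.00186) and -3.85 (unadjusted p = 0.00529). None of these 4 genes passed in that setting, with an adjusted p of 0.358 for each.

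Gene order in the ASM904v1 assembly of strain 168 was used to look at the 5 genes on each side of the deleted ones. Of these 14 were measured, 9 called higher and 1 lower, and after median centring 1 higher and 1 lower. Beside rocG these included rocA, rocB and rocC, given above, and the spore polysaccharide genes spsI at 6.54 and 6.95, spsJ at 5.70 and 5.60 and spsK at 6.12 and 4.81, all called higher. Their neighbour spsL, at 3.81 and 5.36, did not pass (adjusted p = 0.0535). Beside gudB, sleB was called lower, ypdA, the nearest measured gene, was at 0.42 and -0.74, and ypbE, ypbF and ypbG were called higher with the wild type at the floor, at means of 7.77, 6.44 and 6.44.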

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

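All tests in this part were chosen only after the result was seen.

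The control spots lie outside the genes compared, and a signal appeared in them: the median of their log2 ratios was 4.19 on array 1, where 9 of 10 had the wild-type channel at the floor, and 3.99 on array 2, where 7 did. Their signals were low, 62.0 units at most on array 1 and 34.0 on array 2, and 1284 and 1148 genes with the wild type at the floor lay above all of them on the respective array. Of the 1328 genes called higher, 669 lay above all control spots on both arrays.

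The pattern they bear on is that nearly all genes past the test were higher in the mutant: of the genes called higher, 98.6% had the wild-type channel at the floor on both arrays, against 42.8% of all genes. That class holds only positive values, and a real rise from an undetected transcript would fall in it too, so the share decides nothing by itself. Background removed too strongly in the wild-type channel, whatever the strain, may account for the pattern, since spots named for other organisms shared the shift at 4.19 and 3.99. A broad rise of transcripts in the mutant cannot be told apart from it: the control spots' median lay above that of the genes on array 2 (3.99 and 2.33) and just under it on array 1 (4.19 and 4.24). Genes with the wild type at the floor on both arrays had medians of 5.69 and 5.52, above the controls. Control RNA may have been added unequally, and no array has the dyes turned.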

How the results depend on the processing

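The restrictions to genes measured in both channels and to genes with the wild type at the floor were chosen only after the result was seen. All other alternatives were fixed beforehand. No paired analysis was possible because each array is itself the comparison of both strains and there is 1 group. A test of each line of a gene was not run, as every gene had 1 line.

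Median centring left 298 genes past the test (50 higher, 248 lower), 1064 higher and 1317 lower by 2-fold on both arrays, 2 lists higher and 1 neighbour of the deleted genes higher. With scaling added these were 336 (80, 256), 1049 and 1313, and 2 lists. Centring moves the 0 of each array by 4.24 and 2.33, and it also took limma's prior degrees of freedom from 1.11 to infinite. The shares of these in the counts of calls were not tested. Quantile normalization, robust eBayes and treat kept the counts of all genes and of higher genes within 1.5 times. An adjusted p of 0.1 gave 70 lower, removal of genes whose arrays differ 190 lower, and a pooled variance 2189 genes (2093 higher, 96 lower). At 1.5-fold 355 were lower on both arrays, and by a mean of at least 2-fold 338. The cause was not tested.

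An estimated correlation gave 0 lists (0 higher, 0 lower; smallest adjusted p = 0.776), random lists 3 higher (the roc genes, glutamate synthase and proline synthesis), and fry, which does not compare a list with other genes, 2 lists (2 higher, 0 lower), the roc genes and glutamate synthase. Of these, 6 of the 7 roc genes and all 3 of glutamate synthase had the wild type at the floor on both arrays. Such values can only be positive, so the higher direction from fry was given beforehand. With random lists of all genes the branched-chain list was not called, and sigma M and the sigma X and sigma V regulons were called lower. Neither of the last 2 lay outside the central 95% among genes measured in both channels. Among genes measured in both channels limma called 0 genes (0 higher, 0 lower; centred, 135 at an unadjusted p of 0.05), and 174 were 2-fold on both arrays (55 higher, 119 lower). Lists called were 3 (0 higher, 3 lower). Centred on their median, these were 0 genes (0, 0), 166 (76, 90) and 3 lists (0, 3). Among genes with the wild type at the floor 0 lists were called (0 higher, 0 lower), the smallest adjusted p being 0.0925. Fewer genes enter these, and genes far from 0 are left out.

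The correlation of the arrays was 0.521 among genes measured in both channels and 0.614 among those with the wild type at the floor, against 0.587. Leaving out 1 array leaves no test, and counts become genes at least 2-fold on the other: 2747 to 3183 genes, 2404 to 2802 higher, 343 to 381 lower, and 3 lists higher without either. Among 94 single genes followed, the sign reversed for rocE (-2.60 centred, -2.53 also scaled; 0.83 when centred on genes measured in both channels), malA (-0.25 and -0.16; 3.18 when centred on genes measured in both channels) and ypdA (-0.74 without replicate 1, 0.42 without replicate 2). Over all genes, 5 called higher turned to a lower sign with centring. Of the 94 genes, median centring ended 42 calls and made 11 more, and quantile normalization ended 1, that of yccG (adjusted p = 0.0723), and made 2 more. Signal over background limits all of this, since 59.5% and 49.5% of genes had no wild-type signal above the floor.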

Other observations

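The tests restricted to genes measured in both channels or with the wild type at the floor, the comparison of bright spots between arrays and that of the genes beside rocG were chosen only after the result was seen. The limma test over all genes was fixed beforehand, and the test of neighbouring genes across arrays was chosen before its result was seen.

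Further lists were looked at among genes measured in both channels, where camera with the preset correlation called none of the 4 given here, although iron uptake and glycolysis had been called lower among all genes. Iron uptake genes of the Fur regulon, such as feuA at -0.93 and -1.08 and feuB at -0.77 and -1.28, had 12 of 18 members below the median of such genes on both arrays (median -0.44 after centring, camera adjusted p = 0.177). Genes of the PerR regulon, which answers to peroxide, had 5 of 8 above it (median 0.62, adjusted p = 0.308), and pyrimidine synthesis genes 5 of 7 (median 0.49, adjusted p = 0.255). Glycolysis genes, with ptsG at -1.28 and -1.12, had 8 of 11 below it (median -0.33, adjusted p = 0.177). Named after its values were seen, malA, a maltose-use gene, was at 2.76 and 3.31 and did not pass the limma test over all genes (adjusted p = 0.0547).

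Genes that share an operon did not always read alike. Beside leuA at -1.80 and -6.22, leuB was at 9.61 and 3.10, and beside hutU at -7.51 and -5.30, hutP was at 6.83 and 6.55. Of the roc genes, rocD was at 8.83 and 8.60, and rocE, next to it in gene order, at 0.55 and 0.82. Such pairs are given as values, and no explanation was tested for them.

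The roc genes rocA, rocF and rocD and the glutamate synthase gene gltB were among the highest values. With the wild type at the floor this rank compares spot signals, and by itself it is no sign of a response to the deletions. The gene rocE, measured in both channels at a mean of 0.69, did not pass the test. It lies next to rocD in gene order, and it had a wild-type signal above the floor where rocD had none. A response and a background shift shared with other genes cannot be told apart. Among random lists of genes with the wild type at the floor the roc list's median lay at percentile 100 and glutamate synthase at 99.6, but this ranks spot signals of different genes and weighs neither for nor against the shift. Bright spots could also be read at the floor: 75.9% of the 439 genes above 8 with the wild type at the floor on array 1 were measured in both channels on array 2, though only 7.58% of 66 in the reverse direction, and the roc and glutamate synthase calls had it on both arrays. For rocA, rocB and rocC, which lie beside rocG and had a mean of 8.38, an effect of the deletion on adjacent genes cannot be told apart from a response, since spot signals of different genes decide nothing between them.

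Ribosomal protein and sigma W genes were lower as lists than other genes measured in both channels. Camera with an estimated correlation called neither (adjusted p = 0.956 for each list), but that form could hardly call any list. Slower growth or less envelope stress in the mutant may be behind the lower lists, and neither was tested. Over all genes measured in both channels, ratios of neighbouring genes correlated across arrays (r = 0.135 over 369 pairs, permutation p = 0.0006). This argues against independent noise of single spots as the only source of such ratios. The pairs were not limited to the ribosomal protein and sigma W genes, so the test does not settle why these lists were lower. A position effect shared by both arrays was not tested. Ratios that fall with spot brightness cannot be told apart, since brightness is known for no gene measured in both channels: among lists of abundant transcripts, motility lay at percentile 80.8 of random lists, glycolysis at 13.1 and ATP synthase at 23.6, none of them at an extreme.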
